A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

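The data are ribosome footprints and mRNA fragments from budding yeast, in 8 libraries: monosome footprints, polysome footprints, global footprints and mRNA, with 2 replicates each. Per the labels' protocols, cells were grown in rich medium at 30 °C to an OD600 of 0.6 and cycloheximide was added to 100 ug/ml 2 min before harvest. Per the labels' protocols, monosome and polysome fractions were taken from a first gradient, digested with RNase I and run on a further gradient, whereas global footprints passed 1 gradient after digestion. Footprints of 26 to 32 nt and mRNA fragments of 20 to 45 nt were taken, and the RNA was depleted of rRNA, per the labels' protocols.

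The deposited table holds raw counts per gene and library, made with TopHat, Bowtie and HTSeq on the sacCer3 genome, per the submitters' processing notes, which give no versions. The strand setting and the treatment of reads with several matches are not stated. The authors' deposited table also holds a log2 fold change and an adjusted p-value per gene from DESeq2, per the file headers; the comparison is not named, and the sign of the log2 values follows monosome over polysome counts. These deposited p-values and log2 fold changes were used only for the comparison of calls.

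Libraries held 4723489 and 6443263 counts (monosome), 8686385 and 7494965 (polysome), 749057 and 552992 (global), and 933252 and 672928 (mRNA). Of 6692 gene identifiers, 6008 matched the R64 reference table by identifier and 684 did not; the latter stayed in the tests without length or position. Gene lengths run from start to end of the gene in that table and so include introns. The 2 libraries of a group were compared by a chi-square test of their counts, and each pair differed by more than sampling noise (chi-square per degree of freedom 5.53, 4.35, 1.46 and 4.02 in the order above), so none was treated as a copy of another.

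Differences were tested per gene with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test on 1 fit of the 8 libraries with 4 groups, TMM factors and Benjamini-Hochberg adjustment, with a threshold of 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic. It restates that test and is not a fitted standard error. The low-count filter filterByExpr (minimum count 10, minimum total 15) kept 5336 genes, of which 72 had no match in the reference table. The design has no treatment, so translational efficiency is a contrast of global footprints with mRNA within this model. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with camera's estimated correlation and fry beside it, adjusted over the lists of a comparison with at least 5 tested members. List tests for monosome or polysome against global footprints were made in addition to those planned.

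The 17 lists were fixed before the data were examined: cytosolic ribosomal proteins, mRNAs with upstream open reading frames, natural targets of nonsense-mediated decay, glycolysis and fermentation enzymes, translation factors, transcription factors, cyclins, proteasome subunits, mitochondrial ribosomal proteins, ribosome biogenesis factors, cell wall proteins, protein chaperones, amino acid biosynthesis enzymes under Gcn4, nuclear-encoded oxidative phosphorylation subunits, programmed frameshift genes, mitochondrially encoded proteins and non-coding RNAs. The rule for named genes was fixed at the same time. It takes the 8 largest changes each way for monosome against polysome and global against mRNA, and the 4 largest for the other comparisons. These had to pass the threshold, have a mean of at least 50 counts and not overlap between groups. It adds up to 2 members each way per list, and always GCN4, CPA1, HAC1, CLN3, HAP4, YAP1, EST3, OAZ1 and ABP140. Some genes named by the lists are left out of the text. Counts are not given for every list, mainly in monosome or polysome against global footprints. For a gene at 0 in a group, a bound against 3 counts per library is given; with 1 to 3 counts, a ratio with a counting interval.

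Relations across genes used Spearman's rho and Pearson's r with 100000 permutations (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). After the values were seen, list medians on the TMM scale were compared with 10000 random lists of other genes, drawn to match the list in 20 bins of gene length. The weight of monosomes in global footprints minimised squared differences of log2 CPM with a pseudocount of 10 CPM. The pseudocount was first 1 CPM. It was raised because simulated mixtures with a weight of 30% returned 25.2% with the first value and 28.7% with the other. In the libraries themselves the order was reversed, at 31.9% with the first value and 27.4% with the other. The simulation therefore does not settle the choice. The scripts were tested on simulated counts: of genes changed by 0.5, 1 and 2 on the log2 scale, edgeR called 76.5%, 100% and 100% for monosome against polysome, 41.2%, 84.8% and 100% for monosome against global, 38.2%, 83.3% and 98.5% for polysome against global, and 17.6%, 45.5% and 86.4% for global against mRNA. These genes were drawn among those with a mean of at least 50 counts, and most other genes were unchanged. The rates need not hold for the real libraries, where far more genes passed.

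Alternatives were RLE size factors, library totals only, TMM factors from genes other than cytosolic ribosomal proteins, no low-count filter, a mean of at least 100 counts, fits of fewer libraries, replicate number as a block, DESeq2 1.42.0, and leaving out each library. A lone library left in a group is then assumed to vary like the other groups. No genome came with the data, so GC content was not examined.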

Results

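Budding yeast (Saccharomyces cerevisiae) grown in rich medium at 30 °C to an OD600 of 0.6 was treated for 2 min with cycloheximide, a drug that stalls elongating ribosomes. Ribosome footprints, the short mRNA pieces that a ribosome shields from RNase, were sequenced from single ribosomes (monosomes), from mRNAs carrying several ribosomes (polysomes) and from the unfractionated extract (global footprints), beside fragmented mRNA. Each of the 4 groups had 2 libraries. Values below are CPM (counts scaled to a common library size) after TMM scaling, as mean ± SD over the 2 libraries of a group. The labels do not say that these came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

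Libraries of the same group resembled each other. Pearson's r across genes was 0.994 between the monosome libraries, 0.996 between the polysome libraries, 0.959 between the global libraries and 0.942 between the mRNA libraries. Between groups, r was 0.938 to 0.945 for monosome and polysome libraries, 0.956 to 0.965 for polysome and global libraries, 0.910 to 0.926 for monosome and global libraries, and 0.645 to 0.652 for global and mRNA libraries.

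The first comparison asked which genes had a higher TMM-scaled level in monosome than in polysome footprints. It does not tell in which fraction most footprints of a gene lie. Among genes with a mean of at least 50 counts, the largest excess in monosomes was in MIN10, a gene of 264 nt (chromosome VI, 223710 to 223973, R64 assembly), at 78.5 ± 5.50 CPM in monosomes and 6.59 ± 0.0777 CPM in polysomes (n = 2 each; log2 fold change 3.57, SE 0.15, edgeR adjusted p = 1.33e-39). YDR034C-A, YOL014W, YJL118W, YPR002C-A, RMD6, HXT8 and YNL162W-A followed, with log2 fold changes of 3.19, 3.16, 3.01, 2.99, 2.98, 2.98 and 2.97. At the other end lay TPM1, the major tropomyosin of actin cables (chromosome XIV, 478566 to 479165), at 105 ± 3.89 CPM in monosomes and 576 ± 23.5 CPM in polysomes (log2 fold change -2.45, SE 0.11, edgeR adjusted p = 2.93e-37). ENO2, a glycolytic enolase, was at 4851 ± 347 CPM in monosomes and 22272 ± 1859.6 CPM in polysomes (-2.20, SE 0.15, edgeR adjusted p = 1.33e-24). HCR1, an initiation factor subunit (-2.05), RAD23, a proteasome shuttle, NOP1, the methyltransferase of box C/D snoRNPs (-1.95), the actin-binding protein gene ABP1 (-1.94), NHP6A (-1.87) and the aspartyl-tRNA synthetase gene DPS1 (-1.87) were also lower in monosomes. NHP6A overlaps another annotated gene, YPR053C, over 187 nt, so its reads could belong to either.

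Genes with known regulation of translation fell on both sides. GCN4, the activator of amino acid synthesis genes behind upstream open reading frames, was at 84.7 ± 7.81 CPM in monosomes and 20.2 ± 3.43 CPM in polysomes (log2 fold change 2.07, SE 0.12, edgeR adjusted p = 1.11e-28). The G1 cyclin gene CLN3 (1.01, SE 0.12) and the respiratory activator gene HAP4 (0.91, SE 0.17) were also higher in monosomes, whereas YAP1, an activator of oxidative stress genes, was lower (-0.76, SE 0.11). HAC1, whose unspliced mRNA is held silent by base pairing, had a log2 fold change of -0.02 (SE 0.20, edgeR adjusted p = 0.930), and CPA1, whose leader encodes an attenuator peptide, one of -0.08 (SE 0.10, edgeR adjusted p = 0.475). With library totals in place of TMM factors both turned positive and passed, at 0.43 for HAC1 and 0.37 for CPA1. Of 25 tested mRNAs with upstream open reading frames, 11 rose and 6 fell, among them ARV1 (1.87) and FOL1 (-0.90), and the list did not pass (camera adjusted p = 0.582, adjusted p = 0.690 with an estimated correlation). Of 16 natural targets of nonsense-mediated decay, 8 rose and 0 fell with edgeR (0 fell at an unadjusted p under 0.05 and 0 with DESeq2), with EST1 at 1.90 and REV7 at 1.55. This list did not pass either (camera adjusted p = 0.0664, adjusted p = 0.187 with an estimated correlation), although its median of 1.00 lay above the 5th to 95th percentile of random lists of genes of the same lengths (-0.35 to 0.46). With fry, which does not set a list against other genes, it passed (fry adjusted p = 0.00381). The 3 genes with programmed frameshifts split, with the telomerase subunit gene EST3 (1.53, SE 0.14) and the antizyme gene OAZ1 (1.26, SE 0.23) higher and ABP140 (-1.59, SE 0.10) lower.

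Several functional lists were lower in monosomes. Of 21 glycolysis and fermentation enzymes, 20 fell and 0 rose with edgeR (0 rose at an unadjusted p under 0.05 and 0 with DESeq2), with a median log2 fold change of -1.39 and ENO1 at -1.84. Protein chaperones fell in 35 of 42 genes (median -1.04), including the chaperonin subunit gene CCT6 (-1.66), while KAR2, the Hsp70 of the endoplasmic reticulum lumen, rose (1.34, SE 0.11). Translation factors fell in 35 of 41 (median -0.83), with HCR1 and FUN12 (-1.60) lowest, and SUI1 (0.51) was 1 of 2 members that rose. Amino acid biosynthesis enzymes under Gcn4 fell in 39 of 50 (median -0.75), with ARG1 at -1.49 and ARG8 at 1.19. Ribosome biogenesis factors fell in 63 of 77 (median -0.70), and the short gene NOP10 rose (1.41). Proteasome subunits fell in 27 of 32 and rose in 2 (3 adjusted over the list alone) (median -0.69), with RPN10 at -1.40 and RPN7 at -1.28. Camera adjusted p values of these 6 lists, in the order given, were 2.65e-11, 3.13e-11, 1.53e-11, 1.95e-09, 3.78e-10 and 1.43e-08. With an estimated correlation none of the 6 passed, at camera adjusted p values of 0.121, 0.0559, 0.0718, 0.187, 0.104 and 0.0559. All 6 passed with fry, at fry adjusted p values from 7.28e-05 to 0.00126. With library totals only the 6 medians, in the order given, were -0.93, -0.59, -0.38, -0.29, -0.25 and -0.24, against 0.50 over all genes.

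Other lists were higher in monosomes. Of 22 cyclins, 16 rose and 0 fell with edgeR (0 fell at an unadjusted p under 0.05 and 0 with DESeq2), with a median of 0.58 and CLG1 at 1.63 (camera adjusted p = 0.00145, adjusted p = 0.0718 with an estimated correlation). Mitochondrial ribosomal proteins rose in 41 of 71 genes and fell in 8 (median 0.36), with MRP10 at 2.06 and MRP35 at 1.70 (camera adjusted p = 0.00378, adjusted p = 0.0718 with an estimated correlation). The lowest member of that list was MRP8 (-1.22), which may not be a mitochondrial ribosomal protein. Cell wall proteins rose in 16 of 28 and fell in 8 (median 0.39), with the protease gene YPS1 at 1.46 and PST1 at 1.39 (camera adjusted p = 0.0230, adjusted p = 0.653 with an estimated correlation). Cytosolic ribosomal proteins fell in 63 of 137 genes and rose in 30, with a median of -0.20 that turned to 0.25 with library totals only (camera adjusted p = 0.00762, adjusted p = 0.690 with an estimated correlation). The camera call for ribosomal proteins was lost without monosome replicate 2 (adjusted p = 0.162), without polysome replicate 1 (0.0684) and among genes with a mean of at least 100 counts (0.643), where camera's direction also turned to higher. RPL41A (2.93) and RPL41B (2.88), near-identical genes of 78 nt that may share reads, rose most within it, and RPL13A (-1.38) and RPL3 (-1.27) fell most. Transcription factors rose in 33 (31 adjusted over the list alone) and fell in 22 (21 adjusted over the list alone) of 103 genes, with NRG1 at 1.73, RAP1 at -1.06 and a median of -0.02 that turned positive with RLE size factors or library totals (camera adjusted p = 0.582; 0.0278 among genes with a mean of at least 100 counts, where it was 0.176 with an estimated correlation). Nuclear-encoded subunits of oxidative phosphorylation rose in 16 and fell in 15 of 39, with QCR9 at 2.17, QCR6 at -1.14 and a median of 0.00 that turned negative with TMM factors from genes other than ribosomal proteins (camera adjusted p = 0.618). The medians of mitochondrial ribosomal proteins and cell wall proteins lay within the 5th to 95th percentile of random lists of genes of the same lengths (0.01 to 0.42 and -0.31 to 0.41), that of cyclins above it (-0.37 to 0.44) and those of cytosolic ribosomal proteins (0.03 to 0.36) and oxidative phosphorylation subunits (0.23 to 0.79) below it. Here and below, list counts were the same adjusted over the list alone unless another count is given.

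Across 5336 genes tested, 1954 were higher and 1790 lower in monosomes than in polysomes with edgeR, 915 and 426 of them by at least 2-fold. With library totals only, the median over all genes moved from 0.05 to 0.50 and the calls became 3030 higher and 867 lower, so directions here are relative to the TMM scale. In the authors' deposited table, 1483 genes were higher and 1654 lower at an adjusted p under 0.05. Of 5249 genes with a p-value in both, 3066 were called in the same direction, 0 in opposite directions, 665 with edgeR only and 26 in the deposited table only. The fold changes correlated with r = 0.961 across 5326 genes.

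**Figure D1:**
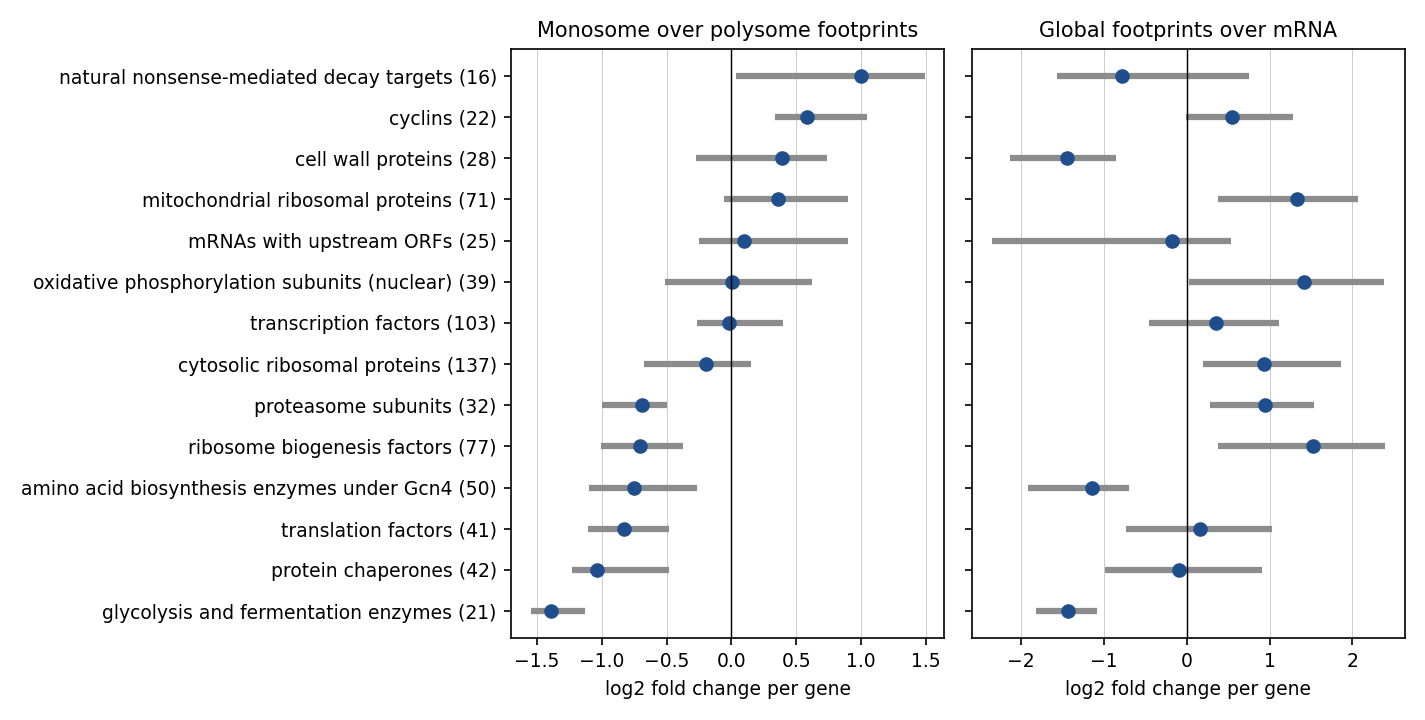
Log2 fold change per gene for lists fixed before the data were examined, with tested members in brackets: monosome over polysome footprints (left) and global footprints over mRNA (right). Points are list medians and bars run from the lower to the upper quartile. On the left, the medians of cytosolic ribosomal proteins and transcription factors turn positive with library totals only, and that of oxidative phosphorylation subunits turns negative with TMM factors from other genes than ribosomal proteins; on the right, those of protein chaperones and of mRNAs with upstream open reading frames turn positive with library totals only.

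Short genes took a larger share of the monosome footprints than of the polysome footprints. The median log2 fold change of monosomes over polysomes was 1.12 among 161 genes of up to 300 nt, of which 128 were higher and 7 lower in monosomes, and 0.33 among 638 genes over 300 and up to 600 nt. It was -0.01 among 1689 genes over 600 and up to 1200 nt, 0.02 among 1935 genes over 1200 and up to 2400 nt and -0.18 among 841 genes over 2400 nt; with library totals only the last became 0.28 and that of genes over 600 and up to 1200 nt 0.44. Across 5264 genes, the ratio of monosome to polysome footprints fell with gene length (Spearman's rho -0.177, Pearson's r -0.230). It also fell with mRNA abundance per kb of gene length (rho -0.228, r -0.246). The same held for translational efficiency, the ratio of global footprints to mRNA (rho -0.156, r -0.165, 5336 genes). Each of these 3 relations had a permutation p of 1e-05, the smallest that 100000 permutations can give, and a Benjamini-Hochberg adjusted p of 1e-05 over the family of 3; genes are not independent replicates. In the replicate 1 and replicate 2 libraries taken separately, rho with length was -0.191 and -0.159, with abundance -0.230 and -0.213, and with efficiency -0.112 and -0.181. Among genes with a mean of at least 100 counts the relation with efficiency was lost (rho 0.0179, permutation p = 0.320), and that with length was -0.265.

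**Figure D2:**
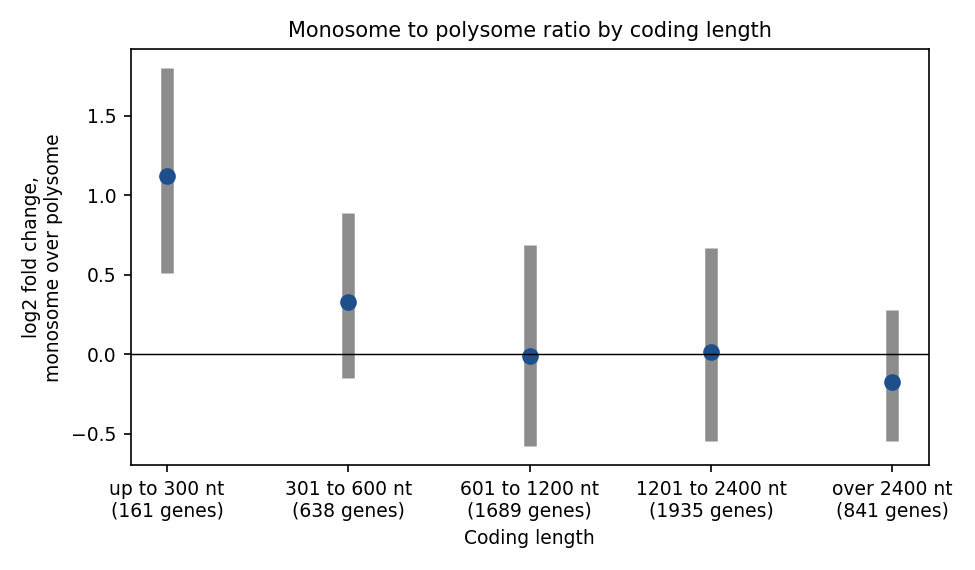
Log2 fold change of monosome over polysome footprints by gene length. Points are medians over the genes of a class and bars run from the lower to the upper quartile. With library totals only, the medians of the class over 600 and up to 1200 nt and of the longest class turn positive.

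Comparing monosome with global footprints asked how single ribosomes differ from the whole. YBL029C-A, a gene of 285 nt, was among those higher in monosomes (45.4 ± 2.36 against 5.40 ± 4.50 CPM, log2 fold change 3.17, SE 0.36, edgeR adjusted p = 1.25e-12), as were MRX19 (2.75, SE 0.48) and the RNA triphosphatase gene CTL1 (2.60, SE 0.35). With 2 and 6 global footprints for YBL029C-A and 4 and 1 for MRX19, their order is not fixed: without global replicate 1 the log2 fold changes were 2.39 and 3.85. HXT8, a hexose transporter family gene with 2 and 1 global footprints, had a TMM-scaled level 8.45 times as high in monosomes (95% counting interval 2.85 to 41.3). GCN4 (1.53, SE 0.20), CLN3 (1.56, SE 0.23) and EST3 (1.69, SE 0.27) were higher in monosomes than in global footprints, and FUN12, the initiation factor that joins ribosomal subunits (-2.10, SE 0.12), and BUD27 (-2.16, SE 0.23) were lower. YAP1 (-0.65, lost without global replicate 2), ABP140 (edgeR adjusted p = 2.51e-13), CPA1 (0.56, lost without global replicate 2) and HAP4 (0.82, lost with DESeq2, with library totals and without monosome or global replicate 2) also passed, and HAC1 (-0.34) and OAZ1 (0.01) did not. Among genes with a mean of at least 50 counts, the largest deficits belonged to YDR278C (2.67 ± 0.0783 against 258 ± 3.49 CPM, -6.57, SE 0.34, edgeR adjusted p = 5.98e-32), YDR445C (-4.08) and YOL013W-A (-3.56), 3 identifiers without a match in the reference table.

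Glycolysis and fermentation enzymes were lower in monosomes than in global footprints in 18 of 21 genes (median -0.89, ENO2 at -1.55), ribosome biogenesis factors in 56 (59 adjusted over the list alone) of 77 (-0.74, UTP14 at -1.90), protein chaperones in 29 (30 adjusted over the list alone) of 42 (-0.74, HSP82 at -1.70) and translation factors in 28 (29 adjusted over the list alone) of 41 (-0.67). Cytosolic ribosomal proteins rose in 78 (80 adjusted over the list alone) of 137 and fell in 15 (16 adjusted over the list alone) (median 0.40, RPL29 at 2.06). Cyclins rose in 11 (12 adjusted over the list alone) of 22 (0.61, PCL5 at 2.03) and mitochondrial ribosomal proteins in 36 of 71 (0.51). Camera adjusted p values of these 7 lists, in the order given, were 5.11e-08, 2.13e-10, 8.41e-09, 5.11e-08, 3.50e-09, 0.000420 and 0.000266. With an estimated correlation none of the 7 passed, at camera adjusted p values of 0.145, 0.0785, 0.0501, 0.0876, 0.322, 0.0501 and 0.0501. Lists left out here also passed camera, among them cell wall proteins (median 0.54, camera adjusted p = 2.75e-05) and proteasome subunits (median -0.64, camera adjusted p = 2.01e-05). With an estimated correlation neither passed (camera adjusted p = 0.264 and 0.0501). Over all genes 1186 were higher and 1295 lower in monosomes with edgeR, 539 and 429 of them by at least 2-fold. The balance turned with the stricter low-count filter (1025 higher and 915 lower) and with fits of the 6 footprint libraries (1334 and 1229) or of these groups alone (1271 and 1235).

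Polysome footprints lay nearer to global footprints. MMF1, a mitochondrial protein gene, was at 2508 ± 33.1 CPM in polysomes and 823 ± 79.0 CPM in global footprints (log2 fold change 1.61, SE 0.12, edgeR adjusted p = 9.23e-20), and YDL012C was at 209 ± 8.17 and 70.8 ± 5.07 CPM (1.55, SE 0.15). Of genes with a mean of at least 50 counts, YDR278C (-6.73), YOL013W-A (-4.56) and YDR445C (-4.08) were again lowest, followed by the siderophore transporter gene ENB1 (-2.20, SE 0.18). Among the regulated genes CPA1 (0.64, lost with library totals or without global replicate 2), OAZ1 (-1.25, lost without polysome replicate 2 or global replicate 1) and ABP140 (0.36, -0.0890 with library totals; also lost with DESeq2, with the stricter low-count filter, and without polysome replicate 1 or either global replicate) passed. Log2 fold changes of GCN4 (-0.53), CLN3 (0.55), HAC1 (-0.31), HAP4 (-0.09), YAP1 (0.11) and EST3 (0.16) did not pass. That of GCN4 passed with library totals (-0.98), with the stricter low-count filter and without polysome replicate 1. Cytosolic ribosomal proteins rose in 107 (115 adjusted over the list alone) of 137 genes and fell in 4 (median 0.65), from RPL36B at 1.47 to RPL41B at -1.78 (camera adjusted p = 4.47e-36, adjusted p = 0.265 with an estimated correlation). With library totals only 64 of them rose and 20 fell (median 0.20). Glycolysis and fermentation enzymes rose in 11 (14 adjusted over the list alone) of 21, with FBA1 at 0.88 and a median of 0.43 that became -0.01 with library totals only (camera adjusted p = 5.06e-06, adjusted p = 0.339 with an estimated correlation). Lists left out here also passed camera, among them amino acid biosynthesis enzymes under Gcn4 (median 0.28, camera adjusted p = 7.15e-05). Nuclear-encoded oxidative phosphorylation subunits did too (median 0.33, camera adjusted p = 0.000543). With library totals only these medians became -0.18 and -0.11. Neither list passed with an estimated correlation (camera adjusted p = 0.369 and 0.0879). With edgeR 720 genes were higher and 534 lower in polysomes, 71 and 236 of them by at least 2-fold. With library totals only the median over all genes moved from -0.02 to -0.46 and the calls became 181 higher and 2002 lower. The number of lower genes was 277 without global replicate 1 and 259 without global replicate 2.

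Global footprints were also described as a mixture of monosome and polysome footprints. The weight of monosomes that best fitted the global libraries was 27.4% (median of the 8 combinations of 1 library each, range 24.1% to 31.8%). No test was made, and the weight was 17.0% on linear CPM, 19.6% among genes with a mean of at least 100 counts and 31.9% with a pseudocount of 1 CPM.

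Comparing global footprints with mRNA gave the translational efficiency of each gene, a contrast within 1 model over both kinds of library. The highest among genes with a mean of at least 50 counts belonged to TMA7, a gene of 195 nt (267 ± 16.6 CPM in footprints and 10.7 ± 4.09 CPM in mRNA, log2 fold change 4.68, SE 0.27, edgeR adjusted p = 6.37e-30). The proteasome lid gene SEM1 (4.18), SAS10 (4.18), the ribosomal protein genes RPS29B (4.15), RPS30A (4.05) and RPS30B (4.03), ELF1 (3.94) and the vacuolar ATPase gene VMA10 (3.88) followed; RPS30A and RPS30B may share reads. HAC1 had 14.0 ± 2.49 CPM in footprints and 3474 ± 508 CPM in mRNA (log2 fold change -7.97, SE 0.21, edgeR adjusted p = 5.92e-57). GCN4 (-3.03, SE 0.21), CLN3 (-2.91, SE 0.24) and CPA1 (-1.91, SE 0.20) had low efficiencies too, while ABP140 (2.41, SE 0.23) and YAP1 (1.57, SE 0.31) had high ones; HAP4 (0.92), EST3 (0.89) and OAZ1 (1.05) did not pass but did with library totals, HAP4 also without global replicate 2 (1.49) and EST3 also without global replicate 1 (1.40). YNL042W-B had 426 and 437 mRNA counts and 0 footprints in both global libraries, which against a floor of 3 counts per library is at least 198-fold lower. By the same floor YGL088W was at least 86.2-fold lower, YFL032W at least 60.4-fold, YMR013W-A at least 58.5-fold and BRE4 at least 55.4-fold. YNL042W-B overlaps a tRNA gene over 84 nt and YGL088W the snoRNA gene SNR10 over 216 nt. Overlaps were looked up only for identifiers with a position in the reference table. YFL032W is numbered next to HAC1 (YFL031W), so its mRNA reads could belong to HAC1.

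**Figure D3:**
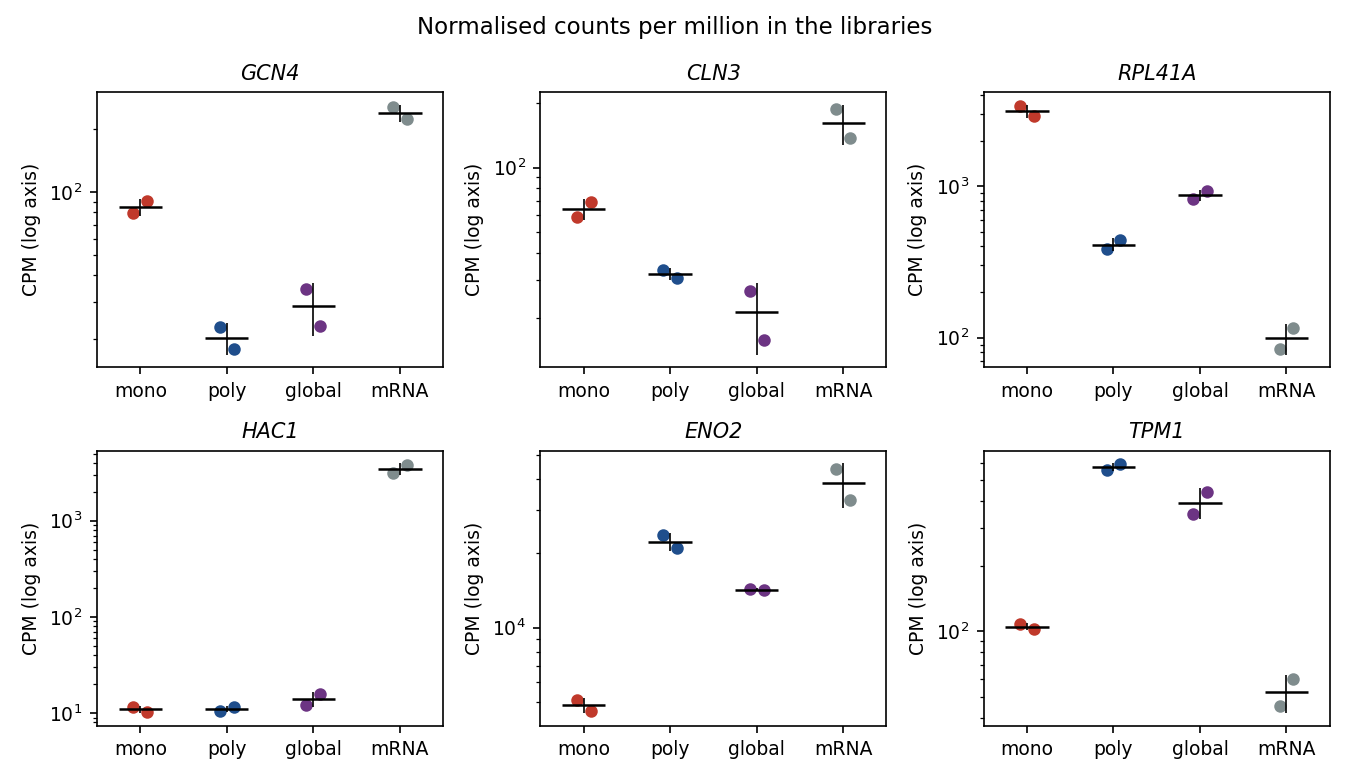
Normalised CPM (log axis) of 6 genes in monosome, polysome and global footprints and in mRNA. Each point is a library, the horizontal line the mean of the 2 libraries and the vertical line their SD. HAC1 had 14.0 CPM in global footprints and 3474 CPM in mRNA; its monosome to polysome ratio turns positive with library totals only.

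Ribosome biogenesis factors had high efficiency, rising in 57 of 77 genes and falling in 14 (median 1.53), with RRP15 at 4.41 and NOP16 at 4.27. Mitochondrial ribosomal proteins rose in 45 (46 adjusted over the list alone) of 71 genes (median 1.33, MRP10 at 5.19), nuclear-encoded subunits of oxidative phosphorylation in 24 of 39 (1.42, or 1.34 with members at 0 placed at their bound), proteasome subunits in 23 of 32 (0.95, RPN13 at 2.40) and cytosolic ribosomal proteins in 100 of 137 (0.94). Low efficiency marked glycolysis and fermentation enzymes, which fell in 18 of 21 genes (median -1.43, PFK2 at -2.46), cell wall proteins, which fell in 23 of 28 (median -1.44, UTR2 at -2.92), and amino acid biosynthesis enzymes under Gcn4, which fell in 40 of 50 (median -1.13, MET13 at -3.13). The mannoprotein genes CWP2 (1.59) and CCW12 (1.22) were cell wall members that rose. RRP15, NOP16 and MRP10 were left out of the ranking above, which required a mean of at least 50 counts and groups that did not overlap. Camera adjusted p values of these 8 lists, in the order given, were 5.76e-06, 2.69e-05, 0.00448, 7.10e-05, 1.61e-08, 4.99e-06, 5.76e-06 and 2.77e-09. With an estimated correlation none of the 8 passed, at camera adjusted p values of 0.242, 0.108, 0.117, 0.117, 0.397, 0.290, 0.303 and 0.242. With library totals only the 8 medians, in the order given, were 2.29, 2.09, 2.18, 1.71, 1.70, -0.66, -0.68 and -0.37, against 0.91 over all genes. Efficiency fell with gene length (rho -0.401), and 4 of the 5 lists that rose had medians within the 5th to 95th percentile of random lists of genes of the same lengths. These ranges were 0.61 to 1.34 for mitochondrial ribosomal proteins, 0.76 to 1.91 for oxidative phosphorylation subunits, -0.13 to 1.03 for proteasome subunits and 0.54 to 1.11 for cytosolic ribosomal proteins. The median of ribosome biogenesis factors lay above its range (-0.38 to 0.37) and those of the 3 lists that fell lay below theirs.

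Cyclins (9 rose and 2 fell of 22), transcription factors (35 (34 adjusted over the list alone) rose and 18 (16 adjusted over the list alone) fell of 103) and translation factors (20 rose and 16 fell of 41) did not pass for efficiency, at camera adjusted p values of 0.292, 0.242 and 0.793. Neither did natural targets of nonsense-mediated decay (2 rose and 5 fell of 16, camera adjusted p = 0.292), although their median of -0.78 lay below the 5th to 95th percentile of random lists of genes of the same lengths (-0.45 to 1.07). The median of transcription factors (0.35) lay above its range (-0.36 to 0.24). Protein chaperones (14 rose and 16 fell of 42, camera adjusted p = 0.659) had a median of -0.09 that became 0.68 with library totals only, and mRNAs with upstream open reading frames (4 rose and 9 fell of 25, camera adjusted p = 0.242) one of -0.17 that became 0.59. In all, 1855 genes had footprints above and 1653 below their mRNA level with edgeR, 1520 and 1294 of them by at least 2-fold. With library totals only the median over all genes moved from 0.15 to 0.91 and the calls became 2906 higher and 1028 lower. The balance turned the other way with RLE size factors (1667 higher and 1798 lower) and with DESeq2 (1565 and 1749). In simulated counts 45.5% of genes changed by 1 on the log2 scale were called in this comparison, against 100% for monosomes and polysomes. Most genes were unchanged there and the changed ones had a mean of at least 50 counts, so these rates need not hold here.

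Mitochondrially encoded genes, whose mRNAs are read by mitochondrial ribosomes, gave 10 and 25 counts in the monosome libraries, 7 and 6 in the polysome libraries, and 88 and 72 in the shallower global libraries. Their share of counts was 0.0117% (exact binomial 95% interval 0.00942% to 0.0145%) and 0.0130% (0.0102% to 0.0164%) in the global libraries and 0.0452% and 0.0456% in mRNA. It was 0.000212% and 0.000388% in the monosome libraries; such intervals cover counting error only. Of 9 tested members, 7 (8 adjusted over the list alone) were lower in monosomes and 7 (8 adjusted over the list alone) in polysomes than in global footprints, and 8 were lower in global footprints than in mRNA (camera adjusted p = 0.00668, adjusted p = 0.151 with an estimated correlation). With members at 0 placed at their bound, the medians against global footprints were -4.71 for monosomes and -6.12 for polysomes over 4 usable members. OLI1, an ATP synthase subunit gene, had 48 and 31 global footprints and 0 in polysomes, at least 118-fold lower. The list of non-coding RNAs had 0 members among the deposited identifiers. The 684 identifiers without a match in the reference table held 4.17% and 7.40% of the mRNA counts, 0.103% and 0.137% of the global footprints and at most 0.0565% of the counts of a monosome or polysome library. An exact permutation test of 2 against 2 libraries cannot reach the threshold at any outcome, so these shares are given as values.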

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

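The pseudocount of 1 CPM was the first setting for the weight and was kept as an added alternative after it was raised. Lengths in multiples of 3 were tried only after the results were seen. Library totals moved the counts most in 3 of 4 comparisons: 3030 higher and 867 lower genes for monosome against polysome, 181 and 2002 for polysome against global, and 2906 and 1028 for global against mRNA. For monosome against global they gave 1177 and 1258, against 823 and 983 without global replicate 1. Library totals also turned HAC1 (0.43) and CPA1 (0.37) for monosome against polysome, ABP140 (-0.0890) for polysome against global, and RPN1 (0.33) and RPT3 (0.36) for global against mRNA; TMM factors are absent there by construction. A mean of at least 100 counts tests fewer genes and gave 1190 and 1118 for monosome against polysome and 1204 and 1082 for global against mRNA; it turned the relation with efficiency to 0.0179, and the cause was not tested. Leaving out 1 library gave 259 to 438 lower genes for polysome against global. List calls went to 0 and 0 with an estimated correlation for monosome against polysome and global against mRNA, and to 14 with fry for the latter. The monosome weight was 17.0% on linear CPM, 19.6% with the stricter filter and 31.9% with a pseudocount of 1 CPM. Replicate number as a block gave 1965 and 1825, 1199 and 1312, 786 and 554, and 1854 and 1652 genes in the order of the report, and correlations of deviations between libraries of the same number ran from -0.00844 to 0.0581. Of 3325 fits of named genes, 3211 kept direction and side of the threshold, 101 lost it, 8 gained it and 5 turned; 24 of 60 genes changed in polysome against global, 14 of 63 in monosome against global, 9 of 70 in monosome against polysome and 8 of 76 in global against mRNA; the cause was not tested.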

Other observations

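Chosen only after the results were seen were the tests of the added lists and families, of lost membrane-bound ribosomes, of counting error, and of low counts and introns among short genes.

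Genes for membrane proteins, in lists chosen after the values were seen, had few footprints for their mRNA. Of 81 transporters of the plasma membrane and vacuole, 76 had lower global footprints than mRNA and 0 higher with edgeR (0 higher at an unadjusted p under 0.05 and 0 with DESeq2), with a median log2 fold change of -2.76 (camera adjusted p = 1.81e-19, adjusted p = 0.0119 with an estimated correlation). Among them were the proton pump gene PMA1 (-2.77, SE 0.14) and the tryptophan permease gene TAT2 (-4.20, SE 0.20). Glycosylation and GPI-anchor enzymes of the endoplasmic reticulum were lower in 34 of 47 genes (median -1.96, camera adjusted p = 0.0253 with an estimated correlation), with the oligosaccharyltransferase gene STT3 at -4.71. Ergosterol and sphingolipid membrane enzymes were lower in 28 of 32 (median -1.62, camera adjusted p = 0.0228 with an estimated correlation), with HMG2 at -3.67. Tail-anchored membrane proteins, inserted after translation, were higher in 28 of 35 (median 2.37, camera adjusted p = 0.0119 with an estimated correlation), with the vacuolar syntaxin gene VAM3 at 4.24 and SSS1 at 3.25. VAM3 did not meet the count and overlap criteria of the efficiency ranking.

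The same lists were also compared between fractions. Tail-anchored membrane proteins were higher in monosomes than in polysomes in 14 of 35 genes and lower in 12, and did not pass (camera adjusted p = 0.507, adjusted p = 0.485 with an estimated correlation). Their median of -0.03 lay below the 5th to 95th percentile of random lists of genes of the same lengths on the TMM scale (-0.01 to 0.60). That median turned positive with RLE size factors or library totals, for which the random lists were not redrawn. Enzymes of glycosylation and GPI anchors were higher in monosomes than in polysomes in 39 of 47 genes (median 1.21, camera adjusted p = 0.0436 with an estimated correlation), with GPI18 at 1.97 and OST4 at 2.92. Transporters were higher in 47 of 81 (median 0.80, camera adjusted p = 0.0683 with an estimated correlation) and ergosterol and sphingolipid membrane enzymes in 25 of 32 (median 0.79, camera adjusted p = 0.0728 with an estimated correlation). Genes with the symbol stem ERG, not chosen as membrane enzymes, were higher in 8 and lower in 11 of 20 (median -0.50). They did not pass (camera adjusted p = 0.284). Soluble aminoacyl-tRNA synthetases were lower in 18 of 19 (median -1.15, camera adjusted p = 1.33e-11, adjusted p = 0.114 with an estimated correlation), with KRS1 at -1.45; their efficiency median of -0.42 became 0.34 with library totals only. Of 39 families of genes sharing a symbol stem, camera called ADE, AIM, ALG, CDC, GPI, MRX, SEC, TMA and TRM for monosome against polysome and ADE, ERG, PHO and RPC for efficiency. No family passed with an estimated correlation, and the medians of CDC and SEC turned positive with library totals only.

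The shortage of footprints of membrane proteins, and of the cell wall proteins above, may come from loss of membrane-bound ribosomes before footprints were taken. It may also come from low translation, and the data do not separate these. Relative to all genes, the transporter median was -2.87 or lower in each of the 3 kinds of footprint. Soluble synthetases lay below all genes too, from -0.56 to -1.56. Their global median of -0.42, however, lay within the 5th to 95th percentile of random lists of the same gene lengths (-1.05 to 0.37), so it decides nothing. With library totals only the synthetase median was 0.34, where that over all genes was 0.91 and random lists were not redrawn. A shortage of every kind of membrane protein is unlikely, since 99.99% of random lists with the same gene lengths had a median as low as that of tail-anchored proteins. Gene length is unlikely as well, since 0% of such lists reached the transporter median. Low counts are also unlikely. Among genes with a mean of at least 100 counts, the median of 30 transporters relative to all such genes was -2.76. Over all tested transporters and genes it was -2.91.

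Mitochondrially encoded genes and names next to tRNA genes were lower in both fractions than in global footprints, which may reflect RNA outside cytosolic ribosomes that the first gradient removed. Identifiers without a match in the reference table were placed by the numbering of neighbouring genes. Of those with at least 100 mRNA reads, 6 of 11 lay next to a tRNA gene, against 42 of 637 others (Fisher's exact p = 4.23e-05). Those 6 held 5.32% of mRNA counts, 0.0896% of global, 0.00467% of monosome and 0.00222% of polysome footprints. The planned test asked whether genes in the reference table that overlap an RNA gene also take a lower share in the fractions. Their share was 1.07 times that of global libraries in the higher fraction, against the hypothesis as predicted. That test says little, since 8 of these 16 genes are translated hosts with 99.98% of the footprints and the rest hold 4 global footprints. Counting error is unlikely for the mitochondrial share, whose lowest 95% bound in global libraries was 16.4 times the highest bound in the fractions.

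The excess of short genes in monosomes may follow from short coding sequences having room for fewer ribosomes, which was not tested apart from other causes. Low counts are an unlikely cause, since rho was -0.265 among genes with a mean of at least 100 counts. Introns inside the lengths are unlikely too, since rho was -0.179 among lengths that are a multiple of 3. The partial rho given efficiency and abundance per kb of gene length was -0.435 (95% bootstrap interval -0.454 to -0.414). Abundance per kb and efficiency alone thus do not account for the relation. With both held fixed, however, length varies with the level of global footprints. The partial rho therefore cannot tell an effect of length from an effect of footprint level. Cytosolic ribosomal proteins could depart from the relation with length: their median of -0.20 may set them apart from other genes of their length. Random lists of such genes had a median of 0.17 (5th to 95th percentile 0.03 to 0.36), with 0% as low. With library totals only the median of ribosomal proteins was 0.25, but that over all genes rose from 0.05 to 0.50 too. The random lists were not redrawn on that scale. Whether ribosomal proteins depart is left open, since random lists treat members as independent. With an estimated correlation of 0.476 the list did not pass (camera adjusted p = 0.690), and camera's direction turned to higher among genes with a mean of at least 100 counts.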
